A study of Mus musculus with 2 samples.

How the data were processed

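Single-cell RNA sequencing was done on subcutaneous tumours of mice given a control diet or a diet free of serine and glycine. Each diet was represented by 1 library, and the number of mice behind a library is not given in the sources used here. The sample titles abbreviate the groups as CT and SG. They were read as control and serine/glycine-free from the series' design text, which names a control diet and a -SG diet. The tumour line and the mouse strain are not given in the sources used here. Per the labels' protocols, tissue was minced, digested with type II collagenase, filtered and treated to lyse erythrocytes, and the libraries followed a 10x Genomics 3' protocol stated to be version 2. The same protocol text speaks of human cardiac septal tissue and of CM cells, which disagrees with the organism and tissue fields (mouse, tumour), so details of the dissociation may belong to another study.

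The deposited values are raw counts of unique molecular identifiers (UMIs, tags that mark each captured RNA molecule) per gene and cell barcode, made by the authors with Cell Ranger. Per the file headers the Cell Ranger version was 7.0.1, whereas per the submitters' processing notes it was 2.2.2 with the mm10 mouse genome. The annotation release and the handling of intronic reads are not given in the sources used here. The deposited matrices listed 32285 genes. The control library held 14774 barcodes and 173785388 UMIs, with a median of 11205 UMIs and 3397.5 genes per barcode. The serine/glycine-free library held 20662 barcodes and 173592046 UMIs, with medians of 7476 UMIs and 2674 genes. The lowest barcode totals were 500 and 501 UMIs, and the total depth of the libraries was nearly the same while the depth per cell was lower in the serine/glycine-free library.

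Cells with at least 500 UMIs, at least 300 genes and at most 20% of UMIs from mitochondrial genes were kept, which left 14159 and 20312 cells. The mitochondrial limit was exceeded by 3.99% of barcodes in the control library and 1.63% in the serine/glycine-free library. Scrublet, run per library in scanpy 1.11.5 with its automatic threshold, then removed 641 (4.53%) and 1571 (7.73%) cells as doublets. The rates expected from the number of cells were 11.3% and 16.2%, so doublets may remain in both libraries. The remaining 13518 and 18741 cells were clustered together with anndata 0.12.19, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and igraph 0.11.9 in Python 3.11.15. Counts were log-normalised, 2000 variable genes and 30 principal components were used, and Leiden clustering on 15 neighbours at resolution 1 gave 21 clusters. No batch correction was applied, so that a difference between the libraries could appear as separate clusters. Figures were drawn with matplotlib 3.10.9.

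Clusters were named from marker panels fixed before the data were examined. A name needed at least 3 panel genes detected in at least 10% of the cluster's cells at 2 times the level of other cells or more, and a mean log2 fold of at least 1 over the panel. These thresholds, unlike the panels, were not laid down in advance. A cluster counted as leukocyte-like when a pan-leukocyte panel was higher in it than in the other cells. T-like cells were clustered again at resolution 1 into 10 subclusters, which needed panel genes at 1.5 times the level of other T-like cells and a mean log2 fold of 0.5. All but CD8 T-like subclusters also needed 1 panel gene among their 10 leading genes. The rule that named CD8 T-like subclusters was set after the data were seen: Cd8a and Cd8b1 each had to be detected in at least 50% of cells and 3 panel genes in at least 10%. Of the 3 subclusters it named, 2 met the fold thresholds as well, and the third, led by mitotic genes (50 and 192 cells), did not. A subcluster of 148 and 214 cells, with Cd8a in 30.4% of cells, met the fold thresholds of the naive/memory panel, had none of its genes among its leading genes, and stayed without a name. The CD8 panel contains Gzmb and Ccl5, so the choice of subclusters is not independent of these genes. A subcluster of 12 and 8 cells led by mast-cell genes was moved out of the T-like class. The subclusters left without a name held 42.7% of T-like cells in the control library and 24.7% in the serine/glycine-free library. No cluster earned an epithelial-like or melanocyte-like name, so the large non-leukocyte clusters without a stromal name were compared as presumed tumour cells, as laid down in advance for that case. B-like and plasma-like cells were joined in 1 class, as were monocyte-like and macrophage-like cells.

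With 1 library per diet there is no replicate check, no test was possible and no p-value was computed. Shares of cells carry exact Clopper-Pearson 95% intervals, and ratios of shares carry 95% intervals from the same counts. For expression, UMIs were summed over the cells of a class in each library and expressed as CPM, that is, scaled to a common total. Ratios are given as log2 of serine/glycine-free over control after adding 1 CPM to each, which understates the change of low genes, with an exact 95% counting interval on the same scale. All these intervals cover counting error only and say nothing of the spread between animals. Those of genes take each UMI as independent, so they are too narrow where few cells hold most UMIs. A gene list was summarised by the median log2 ratio of its members with at least 20 UMIs in both libraries together, by a 95% interval from 2000 bootstrap draws of its members, and by the percentile of its median among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile describes these 2 libraries and is not a p-value. All 20 gene lists were fixed before the data were examined: serine/glycine and one-carbon metabolism, the ATF4 and amino-acid response, glycolysis and lactate, hypoxia, the oxidative-stress (NRF2) response, oxidative phosphorylation, the type I interferon response, the interferon-gamma response with MHC class I, MHC class II presentation, checkpoint ligands, T-cell checkpoint receptors and exhaustion, cytotoxic effectors, naive and stem-like T cells, chemokines, inflammatory macrophages, alternative and lipid-associated macrophages, proliferation, extracellular matrix and EMT, dissociation stress, and lactylation writers and erasers.

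Named genes followed a rule fixed at the same time. It took the 10 highest and 10 lowest log2 ratios in presumed tumour cells and in monocyte/macrophage-like cells, and the 6 highest and 6 lowest in CD8 T-like cells. Genes needed at least 50 CPM in a library, at least 100 UMIs in both together, and a level in the class of at least 50% of that in all other cells, which guards against free RNA. Mitochondrial, ribosomal-protein, haemoglobin, antigen-receptor and predicted genes were left out. The rule also took up to 4 members of largest size per list, the 5 leading genes of each cluster, and Cd274, Pdcd1, Phgdh, Psat1, Shmt2, Ldha, Atf4, Asns, Ifng, Gzmb, Cxcl9 and B2m wherever at least 20 UMIs were found. Gene positions came from GENCODE release M21 on the mm10 assembly, in which 32158 of the 32285 gene identifiers were found, and count from 1. Genes outside the rule (Hmga2, Rhox5, Krt20, Krt18, Epcam, Xist, Ptprc, C1qa, Hbb-bs, Ccl21a, Madcam1 and B-cell genes) were looked up after the data were seen, to describe identity or RNA from other cells.

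The alternatives were a mitochondrial limit of 10%, a minimum of 1000 UMIs per cell, doublets kept, resolutions of 0.5 and 2, cells thinned to 1000 UMIs (shallower cells left out; 31093 of 32259 cells kept), CPM without mitochondrial and ribosomal-protein genes, log2 ratios centred on the median of all genes, a pseudocount of 10 CPM, list members with at least 100 UMIs, and a mean of each cell's CPM. Further alternatives were chosen after seeing the data: shares without B/plasma-like and naive/memory T-like cells, expression without the cell that held most UMIs of a gene in each library, ratios within single clusters of a class for the highest and lowest genes and for dendritic-like lists, a T-like share that counts in an unnamed cluster, and other namings of T-like subclusters (CD8 by fold only, CD8 or naive/memory with unnamed subclusters counted in, and single cells with a Cd8a or Cd8b1 UMI). The statistics were tested on simulated data drawn from the real class sums, with 200 genes changed by known folds. Among unchanged genes, the counting interval held the true value for 94.3% of 16382 genes in presumed tumour cells, 95.9% of 11630 in monocyte/macrophage-like cells and 95.9% of 8657 in CD8 T-like cells. Genes changed by 1.5 times had the right direction in 98%, 98% and 91.7% of cases, and their interval held the true value in 88%, 98% and 95.8%. The simulations covered 16580, 11824 and 8842 genes. The simulation draws counts only, so it does not contain differences between animals or preparations. It also lacks the gathering of a gene's UMIs in single cells, so its coverage does not hold for such genes. Neutrophil-like cells were left out of the comparison of genes. Their median depth was 826 and 677.5 UMIs, and 3 genes typical of the presumed tumour cells stood at a median of 44.4% and 91.7% of their level there. The median log2 ratio of all genes in that class was 0.41, against 0.02 in presumed tumour cells, -0.01 in monocyte/macrophage-like cells and 0.05 in CD8 T-like cells.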

Results

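Single-cell RNA profiles were collected from subcutaneous mouse tumours under a control diet (1 library) and under a diet lacking the amino acids serine and glycine (1 library). After filtering, 13518 control cells and 18741 cells from the serine/glycine-free diet were analysed, carrying 159956647 and 151409580 UMIs. Median depth per cell was 11287 and 7233 UMIs. The comparison addressed how the diet relates to the immune cells in the tumour, to tumour-cell metabolism and to Cd274, the gene of the immune checkpoint ligand PD-L1. Lactylation of the PD-L1 protein, named in the study's title, is not visible in RNA counts. There were no replicates, so every difference is between 2 libraries and has no check against the spread between animals. Intervals are 95%. Those of shares and single genes cover counting error only, and those of list medians cover the spread between a list's members.

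The cells fell into presumed tumour cells, leukocytes and a small stroma. Presumed tumour cells comprised 10 clusters without a marker-based name and made up 79.8% of control cells and 74.4% of cells from the serine/glycine-free diet. They expressed Hmga2, a chromatin protein of embryonic and tumour cells, at 2037 and 1955 CPM, and Rhox5, a homeobox gene often active in mouse tumour lines, at 629 and 611 CPM. Krt20 stood at 148 and 185 CPM and Krt18 at 31.1 and 10.5 CPM, whereas Epcam had 2 UMIs in each library. Xist was at 0.716 and 1.32 CPM in these cells, against 409 and 330 CPM in monocyte/macrophage-like cells. Cluster 0 was led by Ube2c, Prc1, Cenpf, Kif11 and Top2a, which act in mitosis, and cluster 13 by Ube2c, H2afx, Tubb4b, Plk1 and Ccnb1. Cluster 1 was led by Cp, Aspn, Ogn, C1s1 and Dio2, cluster 2 by Dlgap2, Sorcs2, Gria1, Gpr39 and Aox1, and cluster 3 by Lama2, Elovl6, Ung, Nexn and Cldn9. The interferon-induced genes Gbp2b, Ifit3, Gbp2, Gbp3 and Ifit1 led cluster 4. Cdsn, Eno3, Pcolce, Slc9a3r2 and Fkbp11 led cluster 6, and Cdsn, Tenm4, Car6, D5Ertd615e and Angptl6 led cluster 8. Cluster 7 was led by Cryab, Cxcl1, Ndrg1, Bnip3 and Ankrd37, of which the last 3 are hypoxia-induced, and cluster 9 by Gadd45b, Cxcl1, Gadd45g, Cdc20 and Plk2. The most populous of these clusters were 0, 2 and 3 in the control library and 0, 1 and 4 in the serine/glycine-free library.

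Among leukocytes and stroma, the macrophage-like cluster 5 was led by C1qa, C1qb, C1qc, Apoe and Ccl8, and the monocyte-like cluster 10 by Thbs1, Cxcl3, F10, Cxcl2 and Il1b. The T-like clusters 11 and 12 were led by Cd3g, Trbc2, Nkg7, Trbc1 and Tox, and by Gm2682, Skap1, Grap2, Ikzf2 and Gramd3. Granzymes led the NK-like cluster 14 (Gzma, Gzmc, Gzmg, Gzmf and Gzmd), and antibody genes led the B/plasma-like cluster 15 (Igkc, Ighg1, Jchain, Mzb1 and Bank1). Dendritic-like clusters were 16 (Wdfy4, Naaa, Xcr1, Ckb and H2-Eb1) and 20 (Klk1, Siglech, Ccr9, Mctp2 and Rnase6). The neutrophil-like cluster 17 was led by S100a9, S100a8, G0s2, Retnlg and Cxcl2, the fibroblast-like cluster 18 by Col3a1, Cxcl14, Mfap5, Col5a2 and Col1a1, and the endothelial-like cluster 19 by Fabp4, Igfbp3, Gpihbp1, Igfbp7 and Cdh5.

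Leukocytes, and T cells among them, made up a larger part of the serine/glycine-free library. Leukocyte-like cells were 19.1% (18.4 to 19.8) of 13518 control cells and 24.5% (23.9 to 25.1) of 18741 cells from the serine/glycine-free diet, a ratio of 1.28 (1.23 to 1.34). T-like cells were 19.0% (17.5 to 20.6) of 2579 leukocyte-like control cells and 32.8% (31.4 to 34.1) of 4590 in the serine/glycine-free library, a ratio of 1.72 (1.58 to 1.89). Monocyte/macrophage-like cells stood at 60.6% (58.7 to 62.5) and 43.7% (42.3 to 45.2) of leukocyte-like cells, a ratio of 0.721 (0.689 to 0.754). As a share of all cells they were nearer to each other, at 11.6% and 10.7%.

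CD8 T-like cells, the killer T cells of the tumour, numbered 197 of 490 T-like cells in the control library (40.2%, 35.8 to 44.7) and 740 of 1504 in the serine/glycine-free library (49.2%, 46.6 to 51.8). The ratio was 1.22 (1.09 to 1.38) within T-like cells and 2.71 (2.32 to 3.17) as a share of all cells. The direction within T-like cells depends on the naming of subclusters, which was varied after seeing the data. The ratio was 0.901 (0.841 to 0.965) with an unnamed subcluster of 148 and 214 cells counted as CD8 T-like, 0.892 with all unnamed subclusters, and 0.965 (0.890 to 1.05) when counting T-like cells with any Cd8a or Cd8b1 UMI. As a share of all cells CD8 T-like cells were higher under each naming (lowest ratio 1.97, 1.77 to 2.21). Regulatory T-like cells, which restrain other T cells, were 11.8% and 6.65% of T-like cells, but 0.429% and 0.534% of all cells, a ratio of 1.24 whose interval (0.901 to 1.72) holds no difference. Gamma-delta T-like cells were 12 and 8 cells, and T-like cells without a subset name were 42.7% and 24.7%. Per leukocyte, NK-like cells were 7.25% (6.28 to 8.32) and 5.95% (5.28 to 6.67), and dendritic-like cells, which present antigen, were 7.37% (6.39 to 8.44) and 5.40% (4.77 to 6.10). As a share of all cells, NK-like cells were 1.38% and 1.46%, a ratio of 1.05 (0.875 to 1.27). Neutrophil-like cells were 4.50% (3.73 to 5.37) and 3.75% (3.22 to 4.34) of leukocyte-like cells, a ratio of 0.833 whose interval (0.662 to 1.05) holds no difference. In this class, genes typical of the presumed tumour cells stood at a median of 44.4% and 91.7% of their level there. Its cell counts are therefore less certain than the interval shows. Fibroblast-like cells were 0.814% and 0.758% of all cells and endothelial-like cells 0.355% and 0.336%.

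B/plasma-like and naive/memory T-like cells, which circulate and fill lymphoid tissue, were counted beside these shares because they differed most. They numbered 21 and 379 cells, and 14 and 285 cells. With the unnamed subcluster of 148 and 214 cells counted as naive/memory T-like, these were 33.1% and 33.2% of T-like cells, so their difference within T-like cells rests on the naming too. Without them, an alternative chosen after seeing the data, T-like cells were 18.7% and 31.0% of leukocyte-like cells, and CD8 T-like cells were 41.4% and 60.7% of T-like cells. Leukocyte-like cells were then 18.9% and 21.7% of cells, and the per-leukocyte ratios of NK-like cells (0.946, 0.791 to 1.13) and dendritic-like cells (0.846, 0.705 to 1.01) held no difference. Depth per cell was lower in the serine/glycine-free library in each class, at a median of 4087 and 2877.5 UMIs in monocyte/macrophage-like cells and 2807 and 2043 in CD8 T-like cells.

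**Figure D1:**
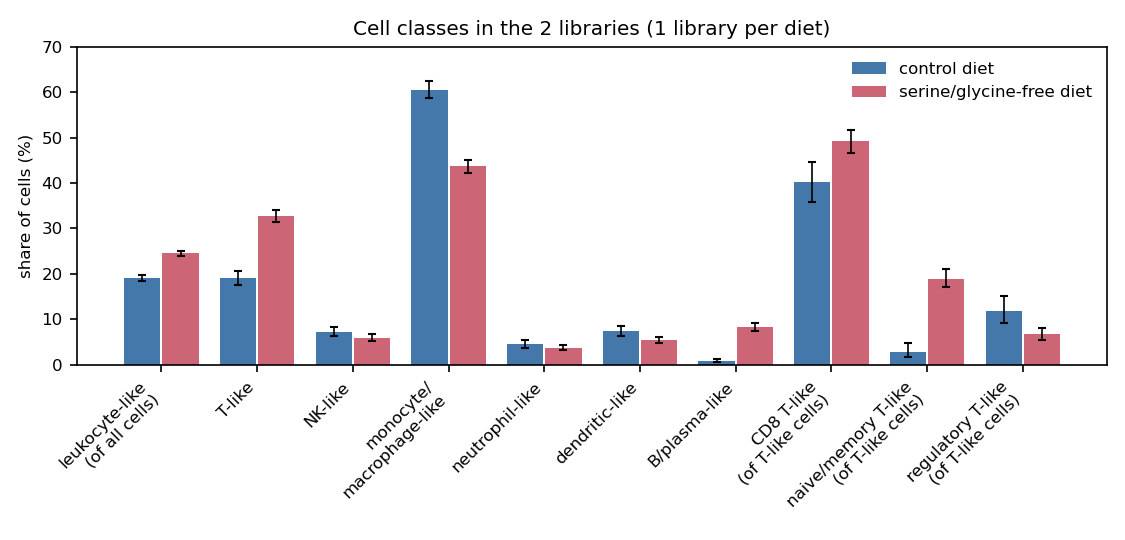
Shares of cell classes (percent of the cells named under each pair of bars) in the control library and the serine/glycine-free library, with bars for the share and whiskers for the exact 95% binomial interval, which covers counting error only. T-like cells stand at 19.0% and 32.8% and monocyte/macrophage-like cells at 60.6% and 43.7% of leukocyte-like cells.

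In presumed tumour cells (148038590 UMIs in the control and 137743002 in the serine/glycine-free library), genes of hypoxia, glycolysis, cell division and the interferon response were higher under the serine/glycine-free diet. All 19 measured hypoxia genes were higher, with a median log2 ratio of 0.55 (0.35 to 0.71) at the 100th percentile of matched random lists. They included Ddit4, an inhibitor of mTOR signalling (10.1 to 24.4 CPM, log2 1.20), Ankrd37 (1.09), the mitophagy receptor Bnip3 (58.1 to 124 CPM, 1.09) and Selenbp1 (0.77). Of 23 glycolysis and lactate genes 19 were higher (median 0.33, 0.10 to 0.43, 100th percentile). Among them were Pgk1 (708 to 1202 CPM, 0.76), Pdk1, which inhibits pyruvate dehydrogenase (0.71), the glucose transporter Slc2a1 (0.58) and the lactate exporter Slc16a3 (0.47). Lactate dehydrogenase Ldha stood at 808 and 1099 CPM (0.44, 0.43 to 0.45). All 28 proliferation genes were higher (median 0.35, 0.32 to 0.41, 100th percentile), as in Ube2c (345 to 529 CPM, 0.62), the mitotic motor Kif11 (0.59), Stmn1 (0.58) and Ccna2 (0.56). Each of these lists had a median above 0 within all 10 presumed tumour clusters.

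Interferon-induced genes were higher in the same cells. The interferon-gamma and MHC class I list had all 30 members higher (median 0.41, 0.32 to 0.55, 100th percentile), with the GTPases Iigp1 (50.7 to 127 CPM, 1.31), Gbp4 (30.3 to 62.3 CPM, 1.02), Igtp (0.89) and Gbp5 (0.86) the largest. Cd274 stood at 12.8 and 16.3 CPM (0.32, 0.24 to 0.40) and B2m, the light chain of MHC class I, at 1873 and 1991 CPM (0.09, 0.08 to 0.10). Of 30 type I interferon genes 28 were higher (median 0.32, 0.26 to 0.41, 100th percentile), among them Ly6a (101 to 224 CPM, 1.14), Rtp4 (0.80), Ifi27l2a (0.65) and Ifit3 (0.56). Within clusters, the interferon-gamma list was above 0 in 10 of 10 (0.01 to 0.47) and the type I list in 8 of 10 (-0.45 to 0.34). The mean of the type I medians within clusters was 0.10. Its lowest value was in the interferon-led cluster 4 (28 of 30 genes lower), which held 742 and 1989 cells, so the mix of clusters moves with the pooled type I value.

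The serine synthesis and one-carbon genes showed little difference. The list had a median of -0.02 (-0.06 to 0.03), with 10 members higher and 13 lower, at percentile 11.5. Phgdh, which starts serine synthesis, was at 295 and 288 CPM (-0.03, -0.05 to -0.01), Shmt2 at 106 and 108 CPM (0.03), and Psat1 at 91.3 and 107 CPM (0.22, 0.19 to 0.26). The other members of largest size were the glycine decarboxylase Gldc (1.99 to 0.661 CPM, -0.85) and the transporters Slc1a5 (-0.27) and Slc6a9 (-0.26). The ATF4 list, which lack of amino acids normally induces, had a median of -0.10 (-0.14 to 0.12), 10 members higher and 17 lower, at percentile 0.11. Its members included Nupr1 (327 to 191 CPM, -0.77), Ddit3 (185 to 120 CPM, -0.63), Cebpb (0.50), Atf4 itself (361 to 309 CPM, -0.22, -0.24 to -0.21) and Asns (282 to 263 CPM, -0.10). Within clusters this list was above 0 in 4 of 10, with a mean of the medians of -0.007 (lowest -0.12, highest 0.10). The pooled fall was therefore not general to the clusters.

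Oxidative phosphorylation genes had a median of -0.08 (-0.13 to -0.03), with 18 of 24 lower, at percentile 0.81, including Cox6a1 (-0.50), Ndufa4 (-0.42) and Cox5a (-0.33) against Uqcrfs1 (0.32). This median was below 0 in all 10 clusters. The lactylation writers and erasers, enzymes that add or remove lactyl groups, had a median of 0.10 (0.05 to 0.15), with 13 of 16 higher and none beyond Kat5 (0.20), Sirt2 (0.20), Kat2b (0.19) and Hdac2 (0.19), at percentile 92.3. Checkpoint ligands had a median of 0.07, with 11 of 15 higher, at percentile 83.1, and held Cd47, a signal against phagocytosis (412 to 527 CPM, 0.35), and Cd276 (-0.61). The oxidative-stress list had a median of 0.04 (11 of 18 higher, percentile 55.8; Slc7a11 0.32, Hmox1 0.21), which was below 0 without mitochondrial and ribosomal-protein genes. The extracellular matrix list stood at 0.00 (15 higher, 15 lower, percentile 27.5) and the dissociation stress list at 0.02 (13 of 24 higher, percentile 35.3), and both medians changed sign with the scaling. They held Timp1 (1167 to 689 CPM, -0.76), Mmp3 (0.90), Dusp1 (47.3 to 106 CPM, 1.15) and Zfp36 (0.98).

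Lists of leukocyte genes were also higher in presumed tumour cells, mostly at a few CPM or less. MHC class II presentation had 11 of 11 members higher (median 0.60, 0.20 to 1.24), with H2-Ab1 (5.75 to 17.4 CPM, 1.44), H2-Aa (11.3 to 29.8 CPM, 1.33) and H2-Eb1 (1.24). The cytotoxic list had 22 of 24 higher (0.34; Gzmf 1.36, Gzmb 0.561 to 2.08 CPM, 0.98), chemokines 19 of 22 (0.39; Cxcl5 1.41, Ccl8 1.35, Cxcl9 1.72 to 3.16 CPM, 0.61), and inflammatory macrophage genes 18 of 20 (0.33; Saa3 0.85, Tnfaip3 0.79). These 4 lists lay at the 100th percentile. With a pseudocount of 10 CPM their medians were 0.29, 0.063, 0.075 and 0.050 in the order given. Adding 10 CPM shrinks the ratio of genes at so low a level by construction. Over members with at least 100 UMIs the medians were 0.65, 0.45, 0.39 and 0.44. The lists thus rest on genes of low level, though not on those with fewest UMIs. Alternative macrophage genes had a median of 0.16 (19 of 27 higher, percentile 99.99; Fabp4 1.11, C1qa 0.75), naive T-cell genes 0.13 (8 of 13 higher, percentile 98.8; Id3 1.17) and exhaustion genes 0.06 (16 of 21 higher, percentile 89.9; Tox 0.63, Pdcd1 0.108 to 0.407 CPM, 0.34). The naive T-cell median was above 0 within only 3 of 10 clusters (mean -0.03), and Id3 was itself among the leading genes of presumed tumour cluster 1. In the same cells the pan-leukocyte gene Ptprc stood at 1.19 and 2.95 CPM, and leukocyte RNA was estimated at 0.245% and 0.486% of their UMIs.

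Ratios in presumed tumour cells were ranked among the 3243 genes that passed the filters for named genes. The highest in the serine/glycine-free library were Cebpd, a transcription factor (45.7 to 142 CPM, 1.62, 1.58 to 1.66), the BMP target Id1 (1.32), the kinase Sgk1 (1.27), the activin antagonist Fst (1.17) and the neutrophil attractant Cxcl1 (1.17). The glutamate transporter Slc1a2 (1.13), the growth factors Fgf10 (1.10) and Fgf7 (1.02), Bnip3 (1.09) and the glucocorticoid-induced Tsc22d3 (0.97) completed the 10. The lowest were Oplah, an enzyme of the glutathione cycle (50.9 to 19.5 CPM, -1.34, -1.40 to -1.28), Sdccag8 (-1.22), Anxa8 (-1.06), Gpr39 (-1.05), Fkbp11 (-0.95), Tenm4 (-0.93), the immediate-early gene Fosb (-0.88), Lars2 (-0.78), Nupr1 (-0.77) and Lgals7 (-0.77). Several of them also mark clusters that differ in size between the libraries, so a count within clusters was added after seeing the data. All 20 genes kept their direction in 10 of 10 clusters, though some were smaller there, as in Cebpd (0.80 to 1.49) and Tenm4 (-1.07 to -0.04). The clusters come from the same 2 libraries that picked the genes, so this count speaks only to the mix of clusters. When the cell with most UMIs of a gene in each library was left out, none of 103 described genes moved by more than 1.5 times or changed direction in presumed tumour cells. In monocyte/macrophage-like cells 2 of 93 moved, and in CD8 T-like cells 7 of 93 moved and 1 changed direction. In NK-like cells 8 of 82 and in fibroblast-like cells 8 of 83 moved, with 1 change of direction in each, and in dendritic-like cells 2 of 84 moved and 2 changed direction.

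Macrophages of the serine/glycine-free library carried more RNA of antigen presentation and of the interferon-gamma response. In the 1563 control and 2006 serine/glycine-free monocyte/macrophage-like cells (7318789 and 6572485 UMIs), all 10 MHC class II genes were higher (median 0.99, 0.35 to 1.31, 100th percentile; 0.56 with doublets kept), with H2-Aa at 1580.2 and 4065 CPM (1.36, 1.33 to 1.39), H2-Eb1 at 1095 and 2803 CPM (1.36), H2-Ab1 (1.31) and their transactivator Ciita (22.3 to 52.3 CPM, 1.20). All 30 interferon-gamma and MHC class I genes were higher (median 0.46, 0.35 to 0.60, 100th percentile), led by Gbp4 (1.17), Gbp5 (0.98), Gbp2 (0.97) and Gbp3 (0.92). Cd274 was at 173 and 277 CPM (0.68, 0.57 to 0.78), Pdcd1lg2, the gene of PD-L2, at 8.88 and 27.8 CPM (1.55), and Cxcl9, an interferon-gamma-induced attractant of T cells, at 487 and 979 CPM (2.01 times; log2 interval 0.95 to 1.06). The type I interferon list did not share this shift. Its median was -0.02 (-0.09 to 0.06), with 14 of 30 higher, at percentile 41.4, although Ly6a stood at 104 and 437 CPM (2.06), beside Ifi27l2a (-0.49), Zbp1 (0.47) and Ly6e (0.39).

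Chemokines and inflammatory genes of these macrophages moved apart. Ccl5 (20.9 to 126 CPM, 2.54), Nos2, the inducible nitric oxide synthase (9.84 to 50.2 CPM, 2.24), and Acod1 (49.5 to 101 CPM, 1.01) were higher, whereas Ccl24 (117 to 39.3 CPM, -1.55), Cxcl3 (218 to 92.8 CPM, -1.22) and Il6 (-1.13) were lower. The chemokine list had a median of -0.43 (-0.71 to 0.24), with 13 of 19 lower, and the inflammatory list 0.14, with 12 of 20 higher, which joins 0.33 in macrophage-like cluster 5 (12 of 19 higher) and -0.0902 in monocyte-like cluster 10 (9 of 20 higher). Proliferation genes had a median of -0.14 (21 of 28 lower; Tyms -0.47, Plk1 -0.40), one-carbon genes -0.14 (15 of 20 lower; Slc1a4 -0.63) and ATF4 genes -0.15 (18 of 25 lower; Vldlr 0.78, Nupr1 -0.68). Alternative macrophage genes had a median of 0.09 (18 of 29 higher; Retnla 1.73, Cd36 1.22). The last 4 medians and the inflammatory one, like those of checkpoint ligands and lactylation genes, took the opposite sign when doublets were kept, as did Psat1 (31.0 to 24.0 CPM, -0.35), Asns (38.0 to 28.8 CPM, -0.39) and B2m (3239 to 3544 CPM, 0.13). Atf4 was at 139 and 115 CPM (-0.28), Phgdh at 21.9 and 22.8 CPM (0.06), Shmt2 at 28.4 and 26.2 CPM (-0.11) and Ldha at 680 and 794 CPM (0.22).

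In the same class, glycolysis genes had a median of 0.21 (21 of 23 higher; Pfkm 0.74, Pfkfb3 0.59), hypoxia genes 0.23 (0.48 with doublets kept; 14 of 19 higher; Adm 1.32, Ndrg1 0.57), oxidative phosphorylation -0.14 (21 of 24 lower; Cox6a1 -0.39) and dissociation stress -0.14 (17 of 24 lower; Fosb -0.89, Jun -0.72). Checkpoint ligands had a median of 0.08, with Nt5e at 35.7 and 16.0 CPM (-1.11), the oxidative-stress list 0.03 with Hmox1 at 303 and 526 CPM (0.80), and lactylation genes 0.04. Matrix genes had a median of 0.14, T-cell lists 0.19 for exhaustion and 0.16 for naive cells, and the cytotoxic list 0.71, whose granzymes stood below 10 CPM. The matrix median was 0.00285 over members with at least 100 UMIs. Within clusters 5 and 10 the exhaustion median was 0.08 and 0.05. RNA of genes typical of the presumed tumour cells stood at 4.35% and 6.24% of its level there.

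Ratios in macrophages were ranked among the 3257 genes that passed the filters for named genes. Of the 10 highest, Cxcl13, which attracts B cells, had 31 and 357 UMIs (4.24 to 54.3 CPM, 3.40), Fabp4, a lipid carrier, 66 and 431 UMIs (2.73), and Lyz1 161 and 533 UMIs (1.84). The 10 cells with most held 100% and 71.1% of the Cxcl13 UMIs and 45.5% and 81.2% of the Fabp4 UMIs, and 1 cell held 233 of the 431 Fabp4 UMIs, without which and its control counterpart the log2 ratio was 1.80. For Cxcl13 it was 4.41 by the same count. Ccl5, Nos2, Ly6a, Calhm6 (1.45) and the MHC class II genes H2-Aa, H2-Eb1 and H2-Ab1 completed the 10. The lowest were the proteases Mmp9 (162 to 42.6 CPM, -1.90) and Ctsk (197 to 66.5 CPM, -1.55), Fcrls (-1.79), Fgf13 (-1.60), Ccl24, the long noncoding RNA AY036118 (785 to 288 CPM, -1.44), Cxcl3, Cxcl14 (-1.21), Rapgef5 (-1.11) and fibronectin Fn1 (835 to 402 CPM, -1.05). The 10 cells with most held 71.8% and 88.6% of the Mmp9 UMIs and 73.0% and 94.7% of the Ctsk UMIs, and Ctsk was lower in only 1 of the 2 clusters of the class and higher instead with at least 1000 UMIs per cell (0.21) and at resolution 2 (0.23).

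CD8 T-like cells (692116 and 1805102 UMIs) carried more granzyme B and Ccl5 in the serine/glycine-free library, while the checkpoint receptor Pdcd1 differed little under the main naming of subclusters. Gzmb stood at 858 and 1257 CPM (0.55, 0.42 to 0.68), Ccl5, a chemokine of effector T cells, at 318 and 1226 CPM (1.94, 1.74 to 2.15), and Pdcd1 at 618 and 632 CPM (0.03, -0.13 to 0.19). With the unnamed subcluster of 148 and 214 cells counted in, Gzmb stood at 0.45, Ccl5 at 1.23 and Pdcd1 at 0.30 (0.14 to 0.46). Ifng, the interferon-gamma gene, was at 405 and 166 CPM (-1.28, -1.52 to -1.04), but 1 control cell held 156 of its 280 control UMIs. Without the cell with most Ifng UMIs in each library it was at 181 and 159 CPM (-0.19). The cytotoxic list had a median of 0.11 (-0.35 to 0.34), with 13 of 24 higher, at percentile 92.2, and the exhaustion list 0.10 (-0.00 to 0.47), with 14 of 20 higher, at percentile 80.3. Both bootstrap intervals reach 0 or below. The cytotoxic and exhaustion medians were 0.22 and 0.29 with the same unnamed subcluster counted in, and 0.06 and 0.02 with doublets kept. The exhaustion list held Cd160 (80.9 to 136 CPM, 0.74), Entpd1 (194 to 306 CPM, 0.66), Rgs16 (201 to 128 CPM, -0.65) and Tox2, with 0 and 20 UMIs.

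Early-response and heat-shock genes were lower in the same cells. The dissociation stress list, which reports handling of the tissue as well as cell activation, had a median of -0.37 with 19 of 24 lower, below all random lists, and included Hspa1a (26.0 to 4.99 CPM, -2.17), Jun (123 to 31.0 CPM, -1.95), Fos (-1.54) and Fosb (-1.49). Glycolysis genes had a median of -0.13 (14 of 20 lower; Slc2a1 -0.79, Hk1 -0.65), ATF4 genes -0.14 (-0.0166 at resolution 2; 14 of 21 lower; Atf3 -0.72, Ppp1r15a -0.70) and hypoxia genes -0.23 (10 of 14 lower; Kdm3a -0.77, P4ha1 -0.69). With doublets kept the glycolysis median was -0.0122 and the hypoxia median 0.22. Type I interferon genes had a median of 0.23 (14 of 19 higher; Ifit2 2.13, Ifit1 1.63), which lies inside the range of random lists (percentile 95.6) and was 0.0171 with at least 1000 UMIs per cell. Over all T-like cells, unnamed subclusters included, the same list went the other way, with a median of -0.33 (21 of 27 lower) below all random lists. Chemokines had a median of 0.51 over 7 genes (1.04 with doublets kept, 0.98 by the mean of each cell's CPM), proliferation genes 0.11 (0.38 with doublets kept; 19 of 28 higher; Ccnb1 0.66), naive T-cell genes -0.18 over 9 genes (Slamf6 2.08, Ccr7 -1.31), lactylation genes 0.11 (Kat2b 73.7 to 148 CPM) and one-carbon genes 0.09 over 17 (Slc25a32 0.81), the last being -0.0810 by the mean of each cell's CPM. The interferon-gamma and MHC class I list stood at -0.01 (0.12 with doublets kept; 14 of 30 higher), with B2m at 3265 and 2657 CPM (-0.30, -0.37 to -0.22) and Cd274 at 116 and 83.7 CPM (-0.46, -0.86 to -0.06). MHC class II genes had a median of 0.67 over 8 genes, and H2-Aa had 5 and 91 UMIs, in a class where C1qa, a macrophage gene, stood at 15.9 and 37.1 CPM. Phgdh (0.16), Psat1 (-0.27), Shmt2 (-0.16), Ldha (0.01), Atf4 (-0.25) and Asns (-0.31) had intervals that held 0.

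Ratios in CD8 T-like cells were ranked among the 3600 genes that passed the filters for named genes. The highest belonged to Gzma, a granzyme, with 4 and 224 UMIs (4.21), Adarb2 with 2 and 110 UMIs (3.99), Ccl5, Plcl1 (43.3 to 146 CPM, 1.73), Tpst2 (1.36) and Igtp (1.31). The lowest belonged to Xcl1, an attractant of dendritic cells (121 to 24.9 CPM, -2.24), Kit (-1.77), Dscam (373 to 115 CPM, -1.69), Gipc2 (-1.43), the granzyme Gzmc (192 to 75.3 CPM, -1.34) and AY036118 (-1.31). The 10 cells with most held 100% and 74.1% of the Gzma UMIs, 95.2% and 73.3% of the Xcl1 UMIs and 82.0% and 69.9% of the Gzmc UMIs. Without the top cell of each library, Xcl1 stood at -1.39. Adarb2 then had no control UMIs left, so its value of 5.81 rests on the 1 CPM added.

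**Figure D2:**
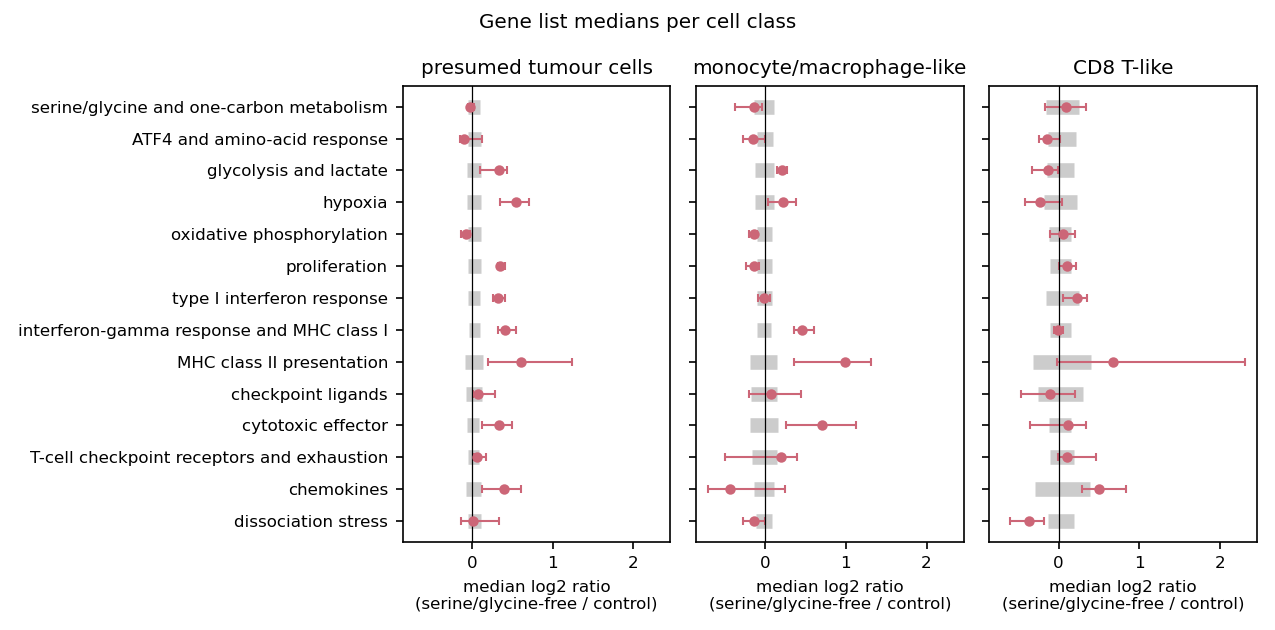
Median log2 ratio of serine/glycine-free over control for gene lists (vertical axis) in presumed tumour, monocyte/macrophage-like and CD8 T-like cells, with points for the median, whiskers for the 95% bootstrap interval over members and grey bars for the central 95% of 10000 random lists matched on expression. The interferon-gamma list lies at 0.41, 0.46 and -0.01 and the hypoxia list at 0.55, 0.23 and -0.23.

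**Figure D3:**
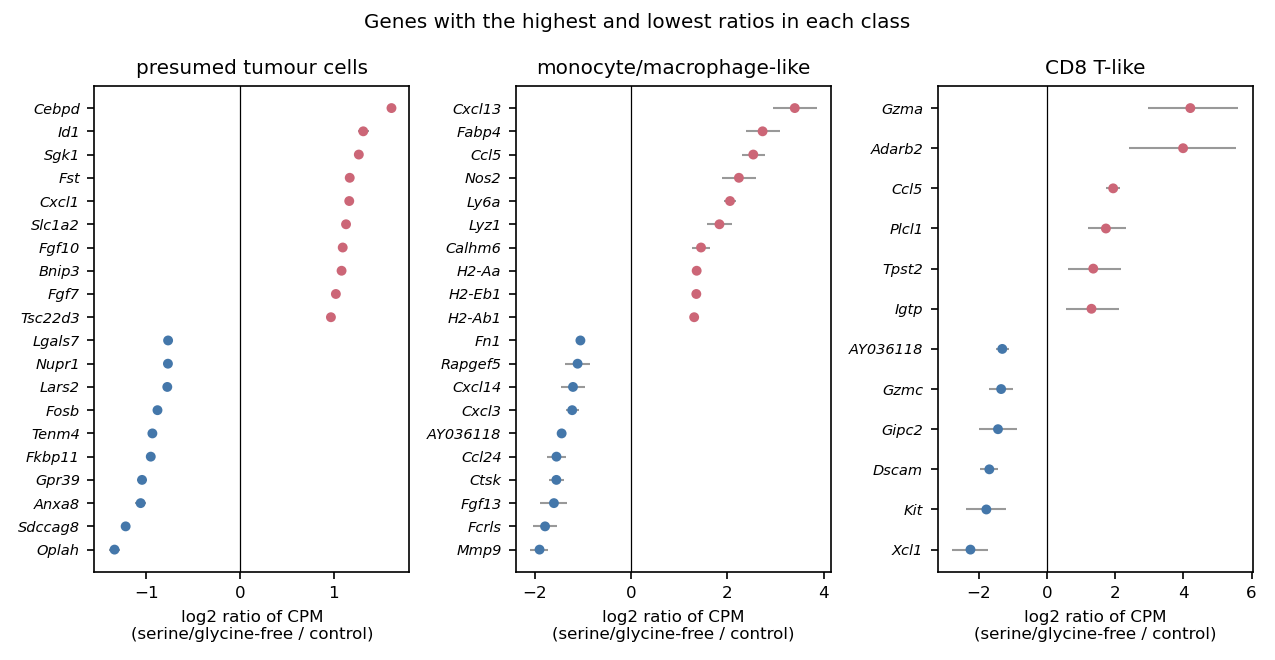
Log2 ratio of CPM (serine/glycine-free over control, 1 CPM added) for the genes with the highest and lowest ratios in each class among those that passed the filters for named genes. Points show the ratio and lines the exact 95% counting interval. Intervals are narrow in presumed tumour cells (Cebpd 1.62, Oplah -1.34) and wide in CD8 T-like cells (Gzma 4.21, 2.96 to 5.62).

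On the mm10 assembly, annotated gene spans of the genes discussed most were as follows, all protein-coding. Cd274 (ENSMUSG00000016496) lies on chromosome 19 from 29367455 to 29388095, and Cebpd (ENSMUSG00000071637) on chromosome 16 from 15887286 to 15891031. Oplah (ENSMUSG00000022562) spans 76296601 to 76328015 on chromosome 15. The MHC class II genes H2-Aa (ENSMUSG00000036594, 34282744 to 34287823), H2-Ab1 (ENSMUSG00000073421, 34257689 to 34269419) and H2-Eb1 (ENSMUSG00000060586, 34305867 to 34316674) are neighbours on chromosome 17. Cxcl9 (ENSMUSG00000029417) lies on chromosome 5 from 92321347 to 92328079, and Ifng (ENSMUSG00000055170) on chromosome 10 from 118441046 to 118445892. Gzmb (ENSMUSG00000015437, 56258838 to 56262260) and Gzmc (ENSMUSG00000079186, 56231441 to 56234656) are both on chromosome 14, and Phgdh (ENSMUSG00000053398) spans 98313170 to 98339990 on chromosome 3. Granzyme genes and the class I MHC genes are families of similar sequence, so UMIs may have been shared among or lost between members at counting.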

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

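All tests of the B-cell and naive T-cell pattern below were chosen only after the result was seen.

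B/plasma-like and naive/memory T-like cells, which no planned comparison used, were more frequent in the serine/glycine-free library, the latter by a factor that depends on the naming of T-like subclusters. B/plasma-like cells were 0.814% of leukocyte-like cells in the control library and 8.26% in the serine/glycine-free library, a ratio of 10.1 (6.55 to 15.7). Naive/memory T-like cells were 2.86% and 18.9% of T-like cells, a ratio of 6.63 (3.92 to 11.2), but 33.1% and 33.2% with an unnamed subcluster of 148 and 214 cells counted in. In the B/plasma-like cells of the serine/glycine-free library, the mature B-cell genes Ms4a1 and Ighd were seen in 194 and 185 of 379 cells and Jchain in 63, counting any cell with 1 UMI.

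A larger number of shallow barcodes in the serine/glycine-free library is not the whole cause: with at least 1000 UMIs per cell the B/plasma-like ratio of shares of all cells was 6.58 (lower bound 3.92), down from 13.02. Lymphoid tissue or blood taken with that tumour stays open. The B/plasma-like and naive/memory T-like ratios of shares of all cells were 13.02 and 14.7, with a quotient of 0.887 (0.443 to 1.77), but with the unnamed subcluster counted in the latter ratio was 2.22 and the quotient 5.86 (3.65 to 9.41), so the test rests on the naming and decides nothing. In the endothelial-like class, Ccl21a and Madcam1, genes of lymphatic and lymph-node vessels, had 0 UMIs in 48 control cells and 101 and 10 UMIs in 63 cells of the serine/glycine-free library, with all Ccl21a UMIs in 1 cell. Haemoglobin Hbb-bs stood at 19.3 CPM over all control cells and 9.16 CPM over all cells of the serine/glycine-free library, which decides little about blood if erythrocytes were lysed as the protocol text states. An effect of the diet on lymphocyte entry, or lymphoid structures inside the tumour, may give either quotient and also stays open, as does any difference between animals.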

How the results depend on the processing

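The settings without B/plasma-like and naive/memory T-like cells, without the cell with most UMIs of a gene, the T-like share with an unnamed cluster counted in, and the other namings of T-like subclusters, were chosen only after the results were seen.

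No paired analysis was possible because each diet has 1 library. The 7 planned share ratios kept their direction wherever they could be computed, except the CD8 ratio with at least 1000 UMIs per cell. No cluster was named neutrophil-like with cells thinned to 1000 UMIs, so that ratio is missing. Of 41 values, 32 lay inside the original interval. With at least 1000 UMIs per cell, the ratio of shares was 1.15 for leukocyte-like, 2.21 for T-like, 0.817 for monocyte/macrophage-like, 0.604 for neutrophil-like and 1 for CD8 T-like cells. The last holds no information, because a low-UMI T cluster of 221 and 363 cells lost its name there and only CD8 T-like cells remained. The T-like value of 2.21 leaves the same cluster out, and with it counted as T-like the shares were 18.5% and 30.2%, a ratio of 1.63 (1.48 to 1.80). With cells thinned to 1000 UMIs the ratio was 1.14 for leukocyte-like, 0.814 for monocyte/macrophage-like and 1.42 for CD8 T-like cells, and with doublets kept it was 1.35 for leukocyte-like cells. Without B/plasma-like and naive/memory T-like cells it was 1.15 for leukocyte-like, 0.832 for monocyte/macrophage-like and 1.47 for CD8 T-like cells, by construction of the cells taken out of numerator or denominator. The CD8 ratio turned to 0.901 with an unnamed subcluster of 148 and 214 cells counted in, 0.892 with all unnamed subclusters and 0.965 by single cells with a Cd8a or Cd8b1 UMI, and was 1.21 by fold only. With unnamed cells counted in this follows from their number, 42.7% of control and 24.7% of serine/glycine-free T-like cells. Elsewhere the cause was not tested.

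All 10 planned list medians kept their sign, and 95 of 100 values lay inside the bootstrap interval. In presumed tumour cells, the mean of each cell's CPM gave -0.15 for ATF4, -0.0668 for one-carbon and 0.28 for proliferation genes, and CPM without mitochondrial and ribosomal-protein genes gave -0.0623 for one-carbon and 0.31 for proliferation genes. The cause was not tested. Of 756 values of named genes, 741 kept their direction, and 5 of the other 15 belonged to genes whose interval left out 0. In monocyte/macrophage-like cells these were Ctsk with at least 1000 UMIs per cell (0.21) and at resolution 2 (0.23), and Psat1 (0.39), Asns (0.15) and B2m (-0.0331) with doublets kept. The cause was not tested, though most Ctsk UMIs sit in 10 cells. Depth limits the small classes, as in CD8 T-like cells with 692116 control UMIs in 197 cells.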

Other observations

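The test of AY036118, the removal of single top cells and the values within dendritic-like clusters were chosen only after the results were seen, and the 3 tests of the interferon-gamma pattern were set before theirs, though the rule for reading the cluster-mix value was revised once after it was seen, with the same outcome.

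Fibroblast-like cells (110 control and 142 serine/glycine-free cells) carried more RNA of the interferon-gamma response and of chemokines in the serine/glycine-free library. All 30 interferon-gamma and MHC class I genes were higher (median log2 ratio 0.74, 0.68 to 0.88), with Gbp4 at 44.5 and 201 CPM (2.15) and Gbp3 at 23.2 and 80.6 CPM (1.76). Of 13 chemokines 12 were higher (median 1.09), among them the neutrophil attractant Cxcl5 (105 to 614 CPM, 2.54, seen in 25 and 59 cells) and Cxcl12, a stromal attractant of lymphocytes (449.5 to 1254 CPM, 1.48). All 27 proliferation genes were higher (median 0.91; Tpx2 2.36) and 21 of 25 ATF4 genes lower (median -0.50; Asns 143 to 75.5 CPM, -0.91). Genes typical of the presumed tumour cells stood at a median of 16.1% and 18.7% of their level there, so tumour RNA may enter these values. Whether the fibroblast-like cells express these genes themselves was not tested. Below, this share is called tumour RNA, whatever its source. Endothelial-like cells (48 and 63) also had higher interferon-gamma response genes (28 of 29, median 0.57) and proliferation genes (22 of 22), beside tumour RNA at 15.5% and 27.5%, and both lists were higher in presumed tumour cells too.

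Dendritic-like cells (190 and 248) had 9 of 12 MHC class II genes lower (median -0.10, -0.28 to -0.02), which lies inside the range of random lists (percentile 8.97). The median was -0.0558 within cluster 16 (153 and 180 cells) and 0.17 within cluster 20 (37 and 68 cells). Of 30 interferon-gamma response genes 24 were higher (median 0.19). Their dissociation stress genes were lower (median -0.48, 19 of 23; Hspa1a 79.6 to 4.63 CPM, -3.84) and their proliferation genes higher (median 0.50, 22 of 27; 0.56 within cluster 16, -0.30 within cluster 20 with 0 of 3 measured genes higher), beside tumour RNA at 4.09% and 7.20%. NK-like cells (187 and 273) had Gzma at 6333 and 10295 CPM (0.70) and type I interferon genes at a median of 0.41 (17 of 20 higher), while one-carbon genes had a median of -0.35 (12 of 15 lower). Their log2 ratio of Ifng, 2.39, rested on 1 cell with 78 of 105 UMIs, and the log2 ratio was 0.69 without the top cell of each library. Tumour RNA stood at 2.24% and 13.4% in NK-like cells.

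Interferon-gamma and MHC class I genes were higher in presumed tumour cells of the serine/glycine-free library (median 0.41). Leukocyte RNA in their droplets brought a median of 2.196% of the added CPM over the 30 members (quartiles 1.36 to 3.88), far below what that explanation needs. With each cell thinned to 1000 UMIs the median was 0.36, so the greater weight of deep cells does not carry the pattern. Thinning leaves a gene's expected part of a cell's UMIs unchanged. The fall predicted under lower depth per cell could therefore hardly occur, and the test does not decide on depth. A different mix of the same clusters is not the whole cause, as the mean of the medians within 10 clusters was 0.22 (0.145 to 0.303), above 0 but with a lower bound under 50% of the pooled value. All 10 clusters come from the same 2 libraries, so this interval says nothing of the spread between animals. A changed mix may account for part, and the clusters were themselves built partly from these genes. What stays open is depth per cell, the diet, a difference between animals, and a difference between the preparations.

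AY036118, a long noncoding RNA on chromosome 17 (39847113 to 39848035), and Lars2, a mitochondrial leucyl-tRNA synthetase gene, were lower in the serine/glycine-free library. Over 8 cell classes the log2 ratio of AY036118 lay between -2.08 and -1.31, and that of Lars2 over 7 classes between -0.78 and -0.14. With the highest value at -1.31, a difference between the 2 preparations that reaches every cell class is a candidate explanation, and it may touch other genes too. An effect of the diet on all cells would look alike and was not tested. No class-specific reading of these genes, or of the stress genes that were lower in CD8 T-like and dendritic-like cells, is offered. Unlike AY036118, the dissociation stress list did not move alike in all classes. Its median was -0.14 in monocyte/macrophage-like and in fibroblast-like cells, 0.02 in presumed tumour cells and -0.002 in NK-like cells. In endothelial-like cells it was 0.42, with 15 of 21 genes higher.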
